A study of Mus musculus with 22 samples.

How the data were processed

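Colon tissue of wild type BALB/c mice was sequenced in 22 libraries, 8 of CON, 5 of DSS, 4 of HMLS and 5 of TM. Per the labels, colon was flash frozen, RNA was extracted with Trizol and libraries were made with the TruSeq Stranded Total RNA kit. The submitters' processing notes name bcl2fastq 2.20, Bowtie without a version, TopHat2 2.0.13, Cufflinks 2.2.0 and the mouse build mm10, with no settings. A total RNA kit also captures transcripts without a poly(A) tail, and TopHat2 and Cufflinks assign reads to annotated genes and divide by transcript length.

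The expression values were deposited by the authors as one table of 23997 genes, and its values were read as FPKM (fragments per transcript length and mapped library size), because the authors' processing notes name Cufflinks and the values carry decimals; the table itself names no unit. The authors also deposited the count of reads and of mapped reads of each library, and the percent of reads mapped. Counts of reads per gene were not analysed here, so a test on counts was not run, and the number of reads behind each gene's value is unknown. Library totals lay between 48089882 and 68733410 reads. Precision therefore rests on the spread between libraries, which the p-values of single genes and of scores per mouse measure. Tests that set the genes of a list against other genes, or that count genes, do not measure that spread alone. That each library comes from a separate mouse is not given in the sources used here, and libraries were treated as mice. Of these genes 2338 were at 0 in every library, 27 names had the form of calendar dates (2 of them more than 1 time) and were kept as listed, and no pair of libraries held identical values. FPKM divides by the library's own total, so a few very abundant genes that rise lower the values of all others.

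Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend and robust variance), and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Folds are on this log2(FPKM + 1) scale, which understates the change of genes near 1 FPKM. Genes were kept with at least 1 FPKM in at least 4 libraries of the fit. Each comparison with CON used its own 2 groups, and HMLS vs DSS, TM vs DSS and HMLS vs TM shared a fit of the 3 colitis groups. Groups came from the labels. The groups, the tests, the filter, 41 gene lists, a panel of 24 genes and the rule for naming genes were chosen before the data were examined. In simulated data a 2-fold change in 50 genes was called in 82% of them for DSS vs CON, 62% for HMLS vs DSS, 74% for TM vs DSS and 84% for HMLS vs TM, and a 1.5-fold change in 56%, 34%, 32% and 20%. The simulated noise was normal and independent between genes, and only genes with a mean log2 value of at least 2 were changed. These rates may therefore be too high for the real libraries and for genes of lower values.

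Genes were named by a rule. For DSS vs CON, HMLS vs DSS and TM vs DSS these were the 8 genes with the largest increase and the 8 with the largest decrease among those past the threshold with a mean of at least 1 FPKM in the higher group, up to 4 members with the smallest p of each list described, and the panel. Where fewer than 3 genes passed, the 3 with the smallest p in each direction are given as values. For the other comparisons the 5 largest changes in each direction and the panel were named. Predicted genes, small RNAs, pseudogenes and antigen receptor segments were left out of the naming. Members of lists named in HMLS vs TM, HMLS vs CON and TM vs CON were chosen after their values were seen. Positions are those of GENCODE M21 on GRCm38, to which 415 of 422 named genes were matched.

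Gene lists were tested against all other genes with camera at its preset correlation of 0.01, and again with a correlation estimated from the data. They were also tested with fry, which asks whether the genes of a list move on balance in one direction and compares them with no other genes. Each p was adjusted over the lists of a comparison. Counts of genes adjusted over the list alone are corrected within 1 list only, not over the 41 lists or the comparisons. With an estimated correlation 1 list was called in DSS vs CON, the intestinal stem cell list, and none in the other 5 comparisons. fry called 15 lists in DSS vs CON, 12 in HMLS vs CON, 13 in TM vs CON, 1 in HMLS vs TM and none in the other comparisons. Scores of lists, the response score and library measures were compared by two-sided exact permutation tests, adjusted within each family. The response score projected each mouse on the DSS against CON fold changes of the 3655 called genes. Shared libraries were handled by simulation and by splitting the shared group.

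Whether the replicate numbers of the titles pair libraries across groups was checked. In TM vs DSS all 3 pairs of the same number correlated above 0.1 after group means were removed (0.137 to 0.432), and the same number was the best match in 1 of 3, so a fit with the number as a block was run for each comparison. It called no gene in the 3 comparisons without CON.

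Alternatives were the pseudocounts 0.1 and 0.01, no filter and a filter of 5 FPKM, median-of-ratios, TMM and quantile scaling, all 22 libraries in one fit, only the groups compared, library weights, an untrended test, a test against a fold of 1.2, the replicate block and each library left out. A limit to mRNA genes, the percent of mapped reads as a covariate, a spread per group and a paired test of the response score of TM vs DSS were added after the data were seen. Further lists of markers were written after results had been seen: general epithelial, morning-phase clock, evening-phase clock, glucocorticoid-induced, canonical histone, collagen and heat shock genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Log2 values are given to 2 decimals and other values to 3 significant digits.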

Results

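RNA from the colon of BALB/c mice was sequenced in 22 libraries that fell into 4 groups. The control group (CON, n = 8) drank distilled water, and the DSS group (n = 5) drank distilled water with dextran sulfate sodium, a polymer that injures the colonic epithelium and is widely used to induce colitis in mice. The HMLS group (n = 4) and the TM group (n = 5) each drank a deep sea water, named by its abbreviation in the labels, and also received dextran sulfate sodium. Per the labels, drinking started at 5 weeks of age and lasted 3 weeks, and dextran sulfate sodium was given at 5% in the last week. The series title places the work in the study of deep sea water as an anti-inflammatory agent in models of inflamed intestinal epithelium.

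The libraries held between 48089882 and 68733410 reads, of which 82.3% to 92.71% were mapped. The share of mapped reads was 91.0% ± 0.711 (SD, n = 8) in CON, 86.6% ± 2.81 (SD, n = 5) in DSS, 89.9% ± 0.762 (SD, n = 4) in HMLS and 91.5% ± 1.27 (SD, n = 5) in TM. All 5 DSS libraries lay below every CON library (two-sided exact permutation test, p = 0.000777, adjusted p = 0.00777 over 30 tests of library measures). TM lay above DSS (exact p = 0.00794, the smallest this design allows, adjusted p = 0.0397). At least 1 FPKM was reached by 13072 ± 129 genes in CON, 12757 ± 280 in DSS, 12669 ± 178 in HMLS and 12872 ± 77.8 in TM (mean ± SD), fewer in each colitis group than in CON (exact adjusted p = 0.0465, 0.0242 and 0.0465). Xist, transcribed from the inactive X chromosome of female cells, lay between 129 and 305 FPKM in all 22 libraries, and 4 genes of the Y chromosome were listed at 0 in all 22. On the first principal component, which carried 32.7% of the variance, every colitis library lay above every CON library.

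The comparison of DSS with CON asked what colitis changed in mice that drank distilled water. Genes of the antimicrobial and acute-phase response were among those that rose most. The secreted lectin Reg3b was at 16030 ± 7180 FPKM in DSS (SD, n = 5) against 1033 ± 531 in CON (SD, n = 8). Its log2 fold change was 4.02 ± 0.391 (SE, adjusted p = 0.0001). The related lectins Reg3g and Reg3a rose by 3.22 ± 0.526 and 2.58 ± 0.372 on the log2 scale, and the acute-phase gene Saa3 by 3.49 ± 0.418. Lcn2, which binds bacterial siderophores, rose 8.02-fold (adjusted p = 0.0116), and S100a8 and S100a9, the calprotectin subunits of neutrophils, by 2.41 ± 0.526 and 2.40 ± 0.44. The stem cell receptor Lgr5 fell by 1.40 ± 0.127 (adjusted p = 7.51e-05), from 2.08 ± 0.478 FPKM in CON to 0.162 ± 0.113 in DSS, and Ascl2, a transcription factor of crypt base stem cells, fell by 1.81 ± 0.201 (adjusted p = 0.000224). Of 13483 genes tested, 3655 passed the threshold, 1889 higher and 1766 lower in DSS, and of these 178 and 184 changed by at least 2-fold.

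The largest increase was that of AI747448, from 2.45 ± 2.41 FPKM in CON to 124.1 ± 176 in DSS (log2 fold change 4.30 ± 0.698, adjusted p = 0.00169), and Ctla2a, which encodes a cysteine protease inhibitor, rose by 2.58 ± 0.446. Among the largest decreases were genes of fat cells. Car3, a carbonic anhydrase abundant in fat and muscle, fell by 4.13 ± 0.741 (adjusted p = 0.00266), from 169.7 ± 137 FPKM to 8.76 ± 8.23. The adipokine Adipoq fell by 2.98 ± 0.606 and Cfd, the complement protease secreted by fat, by 2.54 ± 0.713. The call of Cfd ended without DSS replicate 7 (log2 fold change -2.06, adjusted p = 0.0594). Igj, which encodes the joining chain of IgA and IgM, fell by 3.04 ± 0.611, Nxpe2 by 2.50 ± 0.383, the cytochrome P450 gene Cyp2e1 by 2.95 ± 0.527, the fatty acid desaturase Scd1 by 2.46 ± 0.584 and the colipase gene Clps by 2.17 ± 0.394.

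The changes of DSS against CON are described by gene lists fixed before the data were examined. Of the 15 measured intestinal stem cell genes, 12 fell and 1 rose (camera adjusted p = 2.94e-06; adjusted p = 0.0349 with an estimated correlation), among them Lgr5, Ascl2, the hyaluronan receptor Cd44 (-1.49 ± 0.156) and Tnfrsf19 (-1.33 ± 0.152). This was the only list of 41 that camera also called with an estimated correlation, and adjusted over the list alone 2 of its genes were higher and 12 lower. Of 10 acute inflammation genes, 7 rose and none fell, including the cytokine Tnf (1.53 ± 0.184) and Nos2, the inducible nitric oxide synthase (2.22 ± 0.409). Camera gave an adjusted p of 8.73e-05, and adjusted p = 0.641 with an estimated correlation. With p adjusted over the list alone, 8 were higher. A score of the acute inflammation genes per mouse was 1.40 ± 0.948 in DSS (SD, n = 5) against 0 ± 0.0962 in CON (SD, n = 8), a difference that passed (two-sided exact permutation test, adjusted p = 0.014 over 54 tests). This score used the 15 genes that passed the filter over all 22 libraries, more than the 10 tested here. Of 24 glycolysis and hypoxia genes 13 rose and none fell, such as hexokinase 2 (Hk2, 1.63) and the glucose transporter Slc2a1 (0.78). Camera gave an adjusted p of 1.18e-05, and adjusted p = 0.531 with an estimated correlation, and adjusted over the list alone 15 were higher. Of 22 junction genes 12 rose and 2 fell (camera adjusted p = 0.00158), including the polarity gene Pard6b (1.22) and Cldn4 (1.21 ± 0.2), and of 20 antimicrobial genes 9 rose and 1 fell (camera adjusted p = 0.00318). Both had adjusted p = 0.641 with an estimated correlation, and adjusted over the list alone 12 and 10 were higher and 2 and 2 lower. The 17 clock genes had 7 higher and none lower, also adjusted over the list alone, including Per1 (1.94) and Nfil3 (1.65), with camera adjusted p = 0.0022 and adjusted p = 0.641 with an estimated correlation.

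Of 24 extracellular matrix genes 13 fell and none rose, such as the collagen genes Col3a1 (-1.66) and Col6a3 (-1.25), with camera adjusted p = 1.93e-05 and adjusted p = 0.641 with an estimated correlation. Of 15 adipose genes 9 fell and 2 rose (11 lower and 2 higher adjusted over the list alone), of 10 plasma cell genes 5 fell and 1 rose, and of 11 genes of antigen presentation by MHC class II 5 fell and none rose (7 lower and 1 higher adjusted over the list alone). Camera gave adjusted p values of 0.00585, 0.015 and 0.015 for these 3 lists, and adjusted p = 0.641 with an estimated correlation for each. Named members were the fatty acid binding protein Fabp4 (-2.06), the plasma cell chaperone Mzb1 (-1.46) and the MHC gene H2-Eb1 (-1.09). Of 17 B cell genes 5 fell and none rose (camera adjusted p = 0.00158; adjusted p = 0.641 with an estimated correlation), such as the receptor component Cd79b (-1.75). Of 21 smooth muscle genes 6 fell, including calponin (Cnn1, -1.29), and of 26 proliferation genes 5 fell, including the replication licensing factor Mcm6 (-1.36). Camera gave 0.015 and 0.00488, with adjusted p = 0.691 with an estimated correlation for both. Scores per mouse of B cell, smooth muscle and proliferation genes did not pass (exact permutation test, adjusted p = 0.207, 0.232 and 0.375). Immediate early genes (6 of 15 higher, camera adjusted p = 0.0013), trace metal and redox genes (9 of 30 higher and 1 lower, 0.0241) and endothelial genes (1 of 18 higher and 5 lower, 0.0138) completed the 16 lists called by camera, each with adjusted p = 0.641 with an estimated correlation. Adjusted over the list alone, 7 immediate early genes were higher and 6 endothelial genes lower, and the matrix, plasma cell, B cell, smooth muscle, proliferation and redox lists had the same counts as over all genes. Camera calls ended without DSS replicate 6 for the plasma cell (0.0511) and endothelial lists (0.055), without DSS replicate 5 for MHC class II (0.0744), without DSS replicate 1 for smooth muscle (0.09), and without DSS replicate 2 for the smooth muscle (0.24), endothelial (0.0772) and redox lists (0.0659).

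Several textbook colitis genes did not pass the threshold in DSS against CON. The log2 fold change was 0.31 for the cytokine Il1b (adjusted p = 0.559), -0.18 for Ptgs2 (0.621), 0.71 for Mmp3 (0.227), 0.76 for Mmp10 (0.0929), -0.42 for the mucin Muc2 (0.18), 0.06 for the water channel Aqp8 (0.962), -0.64 for the chloride exchanger Slc26a3 (0.164), -0.51 for Car1 (0.172), -0.52 for Cldn8 (0.197) and 0.14 for the magnesium channel Trpm6 (0.524). Without DSS replicate 7 the value of Il1b was -0.18. Cxcl1, Cxcl5, Il11 and Trpv6 were below the filter on low values. The goblet cell peptide Tff3 (0.60 ± 0.208, adjusted p = 0.0442) and Car4 (1.11 ± 0.371, 0.0392) were higher and the pore-forming claudin Cldn2 (-0.74 ± 0.257, 0.044) lower, but these calls ended when single libraries were left out. The call of Tff3 ended in 10 such settings (adjusted p 0.0529 to 0.113), that of Car4 in 9 (0.0515 to 0.113) and that of Cldn2 in 9 (0.0531 to 0.127), with libraries of both groups among those left out.

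**Figure D1:**
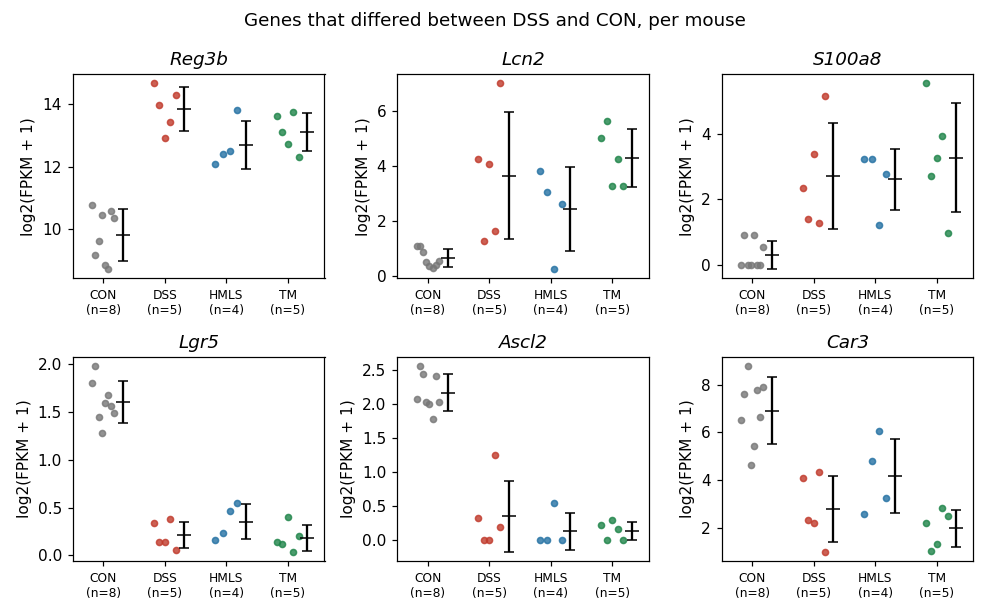
Expression of Reg3b, Lcn2, S100a8, Lgr5, Ascl2 and Car3 in each mouse as log2(FPKM + 1), with a panel per gene and 1 dot per library in CON (n = 8), DSS (n = 5), HMLS (n = 4) and TM (n = 5); the mark and bar beside the dots are the mean and SD. Mean Reg3b was 1033 FPKM in CON and 16030 FPKM in DSS, and mean Lgr5 was 2.08 and 0.162 FPKM.

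The count of DSS against CON was 2493 without DSS replicate 7, 2176 with the replicate number as a block, and 495 when a fold change above 1.2 was required by the test. The share of mapped reads was lower in all 5 DSS libraries, and with it as a covariate 26 genes passed (4 higher, 22 lower). Of the named genes, 129 of the 133 called in this comparison were no longer called, and all 133 kept the sign of their change. The log2 fold changes of the 129 were at a median of 74.9% of their value without the covariate, and 25 had less than 0.5 of that value. The calls lost included those of Lcn2 (1.35, adjusted p = 0.562), S100a8 (1.32, 0.428), Car4 (0.32, 0.806) and Cldn2 (-0.01, 0.996), and that of Cldn4, whose value held at 1.254 (0.132). Reg3b (3.58, adjusted p = 0.0492), Lgr5 (-1.31, 0.03) and Ascl2 (-2.12, 0.03) were still called. Since every DSS library lay below every CON library in this share, the covariate also takes up part of the group difference. The lost calls therefore cannot tell the mapping rate from the colitis. In TM against CON, where the mean share was not below that of CON, 6 of 120 named calls were lost with the covariate.

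The comparison of HMLS with DSS asked whether this water changed gene expression in colitis. The antimicrobial gene Reg3b was at 7497 ± 4680 FPKM in HMLS (SD, n = 4) against 16030 ± 7180 in DSS (SD, n = 5), a log2 difference of -1.14 ± 0.408 with an adjusted p of 0.849. None of 13341 genes passed the threshold of the limma test, while 740 genes (5.55%) had an unadjusted p under 0.05, where chance gives 5%. The smallest p values among genes higher in HMLS were those of the ubiquitin ligase Wwp1 (0.51 ± 0.105), of Scd1 (0.90 ± 0.198) and of the mitochondrial gene Cox8b (1.09 ± 0.26), and among genes lower in HMLS those of the cell cycle inhibitor Cdkn2d (-0.63 ± 0.14), Trim27 (-0.47 ± 0.119) and C2cd4b (-2.02 ± 0.514), each with an adjusted p of 0.849. Other markers of colitis had log2 differences of -1.21 (Lcn2), -0.10 (S100a8), -0.73 (S100a9), -0.20 (Il1b), -0.32 (Cxcl1), -0.23 (Ptgs2), -1.38 (Reg3g), -0.54 (Mmp3) and -0.65 (Mmp10). The other genes of the panel had differences of -0.82 (Muc2), -0.50 (Tff3), -0.33 (Aqp8), 0.67 (Slc26a3), 0.57 (Car1), -0.47 (Car4), -0.67 (Cldn2), 0.52 (Cldn4), 0.12 (Cldn8) and 0.38 (Trpm6), and Lgr5, Cxcl5, Il11 and Trpv6 were below the filter. The difference of Il1b was 0.29 without DSS replicate 7.

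As groups, 17 lists were called by camera in HMLS against DSS, none with an estimated correlation and none by fry. The antimicrobial and the glycolysis lists were lower in HMLS (camera adjusted p = 4.69e-07 for each; adjusted p = 0.149 with an estimated correlation for each), as were the goblet cell list (1.06e-06; adjusted p = 0.221 with an estimated correlation) and the acute inflammation list (0.00136; adjusted p = 0.494 with an estimated correlation). Adjusted over the list alone, 3 antimicrobial genes were lower. They were the peptidoglycan receptor Pglyrp1 (-0.86 ± 0.232), Nos2 (-1.88 ± 0.572) and the peroxide-producing oxidase Duox2 (-1.30 ± 0.406). In the same way 2 inflammation genes were lower, Nos2 and Tnf (-0.84 ± 0.259). In the glycolysis list 1 gene was lower adjusted over the list alone, the oxygen-sensing hydroxylase Egln3 (-0.91 ± 0.234). Lists of fatty acid oxidation (0.000119) and adipose tissue (0.00062) were higher in HMLS, with adjusted p = 0.46 with an estimated correlation for both. These calls ended without HMLS replicate 6 (0.052 and 0.151), and that of acute inflammation without DSS replicate 7 (0.259). Scores per mouse of goblet cell and acute inflammation genes did not pass (exact permutation test, adjusted p = 0.207 and 0.656). Without HMLS replicate 3, Scd1 passed the threshold over all genes (1.14, adjusted p = 0.0459).

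The comparison of TM with DSS asked the same of the other water. Genes of plasma cells and macrophages had the smallest p values among those higher in TM. Mzb1, a chaperone of antibody assembly, was at 2.39 ± 1.59 FPKM in TM (SD, n = 5) against 0.242 ± 0.182 in DSS (SD, n = 5), and Lyz2, the lysozyme of macrophages, at 81.6 ± 22.5 against 39.5 ± 8.26. Their log2 differences of 1.33 ± 0.269 and 1.01 ± 0.234, and that of the B cell coactivator Pou2af1 (1.34 ± 0.298), did not pass the threshold (adjusted p = 1 for each). The smallest p values among genes lower in TM were those of the glutathione-degrading enzyme Ggt1 (-1.18 ± 0.229), of Mall (-0.47 ± 0.127) and of Jund (-0.49 ± 0.138), with the same adjusted p. None of 13341 genes passed the threshold of the limma test, and 367 (2.75%) had an unadjusted p under 0.05, where chance gives 5%. The markers of colitis had log2 differences of -0.74 (Reg3b), -0.66 (Reg3g), 0.64 (Lcn2), 0.57 (S100a8), 0.64 (S100a9), 0.46 (Il1b), 0.997 (Cxcl1), 0.21 (Ptgs2), 0.38 (Mmp3) and 0.17 (Mmp10). For the other panel genes they were -0.12 (Muc2), -0.13 (Tff3), -0.05 (Aqp8), -0.01 (Slc26a3), -0.28 (Car1), -0.54 (Car4), 0.51 (Cldn2), 0.35 (Cldn4), 0.15 (Cldn8) and 0.01 (Trpm6), with Lgr5, Cxcl5, Il11 and Trpv6 below the filter. Without TM replicate 3 the differences of Car4 and Cxcl1 were 0.04 and 0.63, and that of Il1b was 0.95 without DSS replicate 7.

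In TM against DSS camera called 13 lists, and none was called with an estimated correlation or by fry. The macrophage list (4.51e-10), the B cell list (3.46e-09) and the plasma cell list (0.000989) were higher in TM, each with adjusted p = 0.267 with an estimated correlation. Adjusted over the list alone, 3 plasma cell genes were higher (Mzb1, Pou2af1 and Igj, 1.76 ± 0.569) and 1 macrophage gene (Lyz2), while the median over the plasma cell list was 0.05. The glycolysis list was lower (0.000245; adjusted p = 0.267 with an estimated correlation) and the MHC class II list higher (0.000989; adjusted p = 0.429 with an estimated correlation). The extracellular matrix list (0.000342; adjusted p = 0.597 with an estimated correlation) and the metalloprotease list (0.000989; adjusted p = 0.583 with an estimated correlation) were higher, but pointed the other way with the replicate number as a block (0.613 and 0.941). The other lists called were those of endothelial genes (3.31e-05; adjusted p = 0.399 with an estimated correlation) and of NF-kB targets (0.00127; adjusted p = 0.368 with an estimated correlation), among others. Both calls ended with the replicate number as a block (0.102 and 0.0652), as did that of calcium and magnesium genes, lower in TM (0.0446 without and 0.125 with the block). With the block camera also called the lists of smooth muscle (2.47e-06), enteric neuron, glia and interstitial cell (6.54e-06) and clock genes (0.000257) as lower in TM, and those of oxidative phosphorylation (0.0058) and goblet cells (0.0236) as higher. Without the block camera gave adjusted p of 0.673, 0.318, 0.0513, 0.769 and 0.83 for them. The block was run at the preset correlation only. Scores per mouse of B cell and metalloprotease genes did not pass in TM against DSS (exact permutation test, adjusted p = 0.214 and 0.642). Camera calls also ended without TM replicate 3 for the plasma cell (0.237), matrix (0.537) and metalloprotease lists (0.0656), and without DSS replicate 2 for the last 2 (0.395 and 0.0892). The same held for the plasma cell list without TM replicate 6 (0.06), MHC class II without DSS replicate 5 or TM replicate 8 (0.0741 and 0.175), and NF-kB targets without DSS replicate 1 or TM replicate 5 (0.0652 and 0.0847). The camera call of calcium and magnesium genes ended without DSS replicate 2, 5 or 6 (0.0595, 0.148 and 0.0811) and without TM replicate 3 or 6 (0.224 and 0.0643).

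The comparison of HMLS with TM asked whether the waters differed from each other. The smallest p values included those of macrophage genes. Lyz2 was at 33.95 ± 14.4 FPKM in HMLS (SD, n = 4) against 81.6 ± 22.5 in TM (SD, n = 5), a log2 difference of -1.28 ± 0.248, and C1qa, a complement gene of tissue macrophages, differed by -1.53 ± 0.301. The differences of the lymphocyte transcription factor Ets1 (-0.85 ± 0.155) and of Mzb1 (-1.46 ± 0.285) were also negative. Those of Scd1 (0.98 ± 0.198), Wwp1 (0.47 ± 0.105) and Olfr613 (0.62 ± 0.147) were positive. None of 13341 genes passed the threshold of the limma test (adjusted p = 0.278 for Ets1, Lyz2, Mzb1, C1qa and Scd1), and 1260 (9.44%) had an unadjusted p under 0.05. Within the panel, Cldn2 (-1.18, adjusted p = 0.407), Car1 (0.85) and Cxcl1 (-1.32) had the smallest p values, and the others ranged from -1.85 (Lcn2) to 0.67 (Slc26a3). The difference of Car4 (0.06) was -0.51 without TM replicate 3.

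Adjusted over the list alone, 8 of 15 macrophage genes, 8 of 10 MHC class II genes, 7 of 11 B cell genes, 5 of 20 NF-kB targets and 3 of 9 plasma cell genes were lower in HMLS than in TM. None of these genes passed over all genes tested. These counts are not corrected over the 41 lists, and genes of a list are not independent. Examples were C1qc (-1.62), H2-DMb2 (-1.41), H2-Eb1 (-1.31), Pou2af1 (-1.54) and the adhesion molecules Vcam1 (-1.34) and Icam1 (-1.07). Adjusted over the list alone, 4 of 14 adipose genes and 3 of 17 calcium and magnesium transport genes were higher, among them the calcium pump Atp2b1 (0.95), the magnesium transporter Nipa2 (0.54) and the sodium-calcium exchanger Slc8a1 (0.54). Camera called 23 lists, fry 1 (calcium and magnesium transport, 0.0239), and with an estimated correlation none was called, with adjusted p = 0.18 with an estimated correlation as the smallest. A score of goblet cell genes was -0.528 ± 0.176 in HMLS and 0.0469 ± 0.0961 in TM (exact permutation test, p = 0.00794, adjusted p = 0.077 over 54 tests). No list score passed between HMLS and TM. Those of B cell, acute inflammation and metalloprotease genes each had adjusted p = 0.143 by this test. Without HMLS replicate 3 the genes past the threshold were C1qa (-1.88, adjusted p = 0.0153), Lyz2 (-1.53, 0.0341) and Scd1 (1.22, 0.0153).

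**Figure D2:**
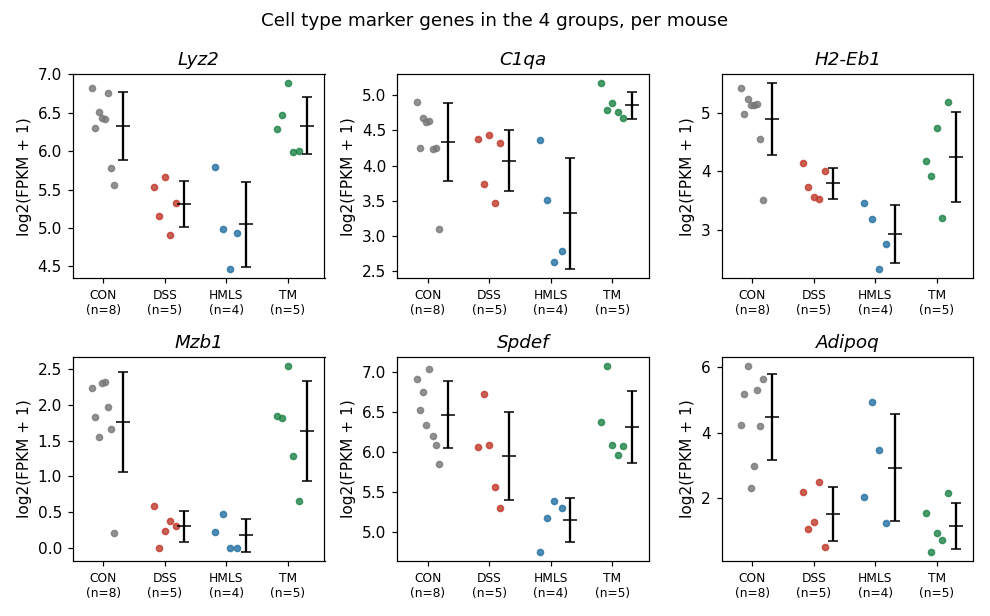
Expression of Lyz2, C1qa, H2-Eb1, Mzb1, Spdef and Adipoq in each mouse as log2(FPKM + 1), with a panel per gene and 1 dot per library in CON (n = 8), DSS (n = 5), HMLS (n = 4) and TM (n = 5); the mark and bar beside the dots are the mean and SD. Mean Lyz2 was 33.95 FPKM in HMLS, 81.6 in TM and 39.5 in DSS, and no gene passed the threshold between these 3 groups.

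The comparisons of each water with CON set mice given the water and dextran sulfate sodium against mice given neither. No group received the water alone, so these comparisons do not separate the water from the colitis. In HMLS, Reg3b rose by 2.88 ± 0.455 on the log2 scale (SE, adjusted p = 0.00103) and AI747448 by 2.88 ± 0.605, Ctla2a by 2.71 ± 0.427, Saa3 by 2.57 ± 0.483 and the ganglioside synthase St3gal5 by 2.38 ± 0.427. Igj fell by 3.36 ± 0.681, Nxpe2 by 3.08 ± 0.452 and the histone genes Hist1h3b and Hist1h2ag by 3.01 ± 0.588 and 2.96 ± 0.481. Mptx2 was lower by -2.92 ± 0.945 (adjusted p = 0.0359), a call that ended in 7 settings without a single CON or HMLS library (adjusted p 0.0517 to 0.0882). Of 13400 genes tested 4565 passed, 2339 higher and 2226 lower, of which 170 and 315 changed by at least 2-fold. The panel genes S100a8 (2.31), Lcn2 (1.79), Reg3g (1.84) and Cldn4 (1.73) rose, and Muc2 (-1.25), Cldn2 (-1.41) and Lgr5 (-1.25) fell. The call of Reg3g ended without HMLS replicate 6 or HMLS replicate 8 (adjusted p up to 0.0754). Il1b (0.10), Ptgs2 (-0.41), Mmp3 (0.17), Tff3 (0.10), Aqp8 (-0.27), Slc26a3 (0.03), Car1 (0.06), Car4 (0.64), Cldn8 (-0.40) and Trpm6 (0.52) did not pass, and S100a9, Cxcl1, Cxcl5, Il11, Mmp10 and Trpv6 were below the filter. Cldn8 passed without CON replicate 8 (-0.50, adjusted p = 0.039).

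Of 24 extracellular matrix genes 17 fell in HMLS against CON, such as Col3a1 (-2.38) and Col1a1 (-1.83), with camera adjusted p = 1.25e-07 and adjusted p = 0.575 with an estimated correlation. Of 15 stem cell genes 10 fell, led by Ascl2 (-2.03, adjusted p = 2.51e-05), with camera adjusted p = 1.88e-06 and adjusted p = 0.125 with an estimated correlation. Of 26 proliferation genes 12 fell, such as Mcm6 (-1.97), of 17 B cell genes 10 fell, and of 17 clock genes 10 rose, such as Per3 (1.22) and the clock output factor Tef (1.54). Camera gave 5.99e-06, 0.000266 and 0.000256 for these, with adjusted p = 0.748, 0.748 and 0.575 with an estimated correlation. Of 19 goblet cell genes 7 fell and 1 rose, including the goblet cell transcription factor Spdef (-1.31; camera 0.0132, adjusted p = 0.717 with an estimated correlation), and of 9 acute inflammation genes 5 rose (0.0319; adjusted p = 0.575 with an estimated correlation). The first of these calls ended without HMLS replicate 6 (0.0535), and the second without CON replicate 8 (0.0597) or HMLS replicate 3, 6 or 8 (0.159, 0.165 and 0.165). The acute inflammation score, over 15 genes, was 0.826 ± 0.479 in HMLS (SD, n = 4) and passed against CON (exact adjusted p = 0.0273). Scores of goblet cell, proliferation and B cell genes did not pass (exact permutation test, adjusted p = 0.109, 0.123 and 0.16). When adjusted over the list alone, 19 matrix, 11 stem cell, 15 proliferation, 13 B cell and 9 goblet cell genes were lower and 11 clock genes higher, and 1 stem cell and 1 goblet cell gene were higher. Of the acute inflammation genes 5 were higher and 1 lower in this way. Camera called 13 lists in all. The count of genes was 753 with the replicate number as a block and 1034 when a fold change above 1.2 was required. With the mapping rate as a covariate 37 of 148 named genes lost their call, among them Lcn2 (1.40, adjusted p = 0.128), Reg3g (1.003, 0.247) and Mptx2 (-3.57, 0.0635). The genes whose calls were lost kept a median of 83.5% of their log2 fold change, and 1 had less than 0.5 of it.

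In TM against CON, Lcn2 rose by 3.64 ± 0.349 on the log2 scale (adjusted p = 4.78e-05), AI747448 by 3.32 ± 0.43, Reg3b by 3.28 ± 0.386, S100a9 by 3.04 ± 0.439 and S100a8 by 2.98 ± 0.56. The adipose genes Car3, Cfd and Adipoq fell by 4.94 ± 0.654, 3.42 ± 0.714 and 3.35 ± 0.606, Cyp2e1 by 3.38 ± 0.627 and the adipokine Retn by 2.88 ± 0.632. Of 13485 genes tested 3510 passed, 1924 higher and 1586 lower, of which 135 and 139 changed by at least 2-fold. The neutrophil chemokine Cxcl1 (1.80), Reg3g (2.56), the stromelysin Mmp3 (1.09) and Cldn4 (1.56) rose, and Lgr5 (-1.43) and Car1 (-0.79) fell, the call of Car1 ending without TM replicate 5 or TM replicate 7 (adjusted p 0.0645 and 0.0706). Il1b (0.77), Ptgs2 (0.02), Muc2 (-0.54), Tff3 (0.47), Aqp8 (0.01), Slc26a3 (-0.64), Car4 (0.58), Cldn2 (-0.24), Cldn8 (-0.37) and Trpm6 (0.15) did not pass, and Cxcl5, Il11, Mmp10 and Trpv6 were below the filter. Car4 passed without TM replicate 3 (1.15, adjusted p = 0.0324), and Cldn8 without CON replicate 8 (-0.47, 0.043).

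Of 15 stem cell genes 10 fell and 1 rose in TM against CON, such as Ascl2 (-2.02, adjusted p = 1.68e-06) and Axin2 (-1.91), and of 11 acute inflammation genes 9 rose. Camera gave an adjusted p of 2.03e-07 for each, and adjusted p = 0.0951 with an estimated correlation for each. The acute inflammation score was 1.68 ± 0.603 and the metalloprotease score 0.691 ± 0.418 in TM (SD, n = 5), and both passed against CON (exact adjusted p = 0.014 for each). These scores used 15 and 17 genes, those kept by the filter over all 22 libraries. Of 13 metalloprotease genes 7 rose, such as the aggrecan-cleaving proteases Adamts1 (2.07) and Adamts4 (2.01), and of 20 NF-kB targets 12 rose and 2 fell, such as the inhibitor Nfkbia (1.33) and the RNase Zc3h12a (1.77). Of 20 antimicrobial genes 9 rose and 1 fell. Camera gave 0.000515, 0.00111 and 0.00205, with adjusted p = 0.421 with an estimated correlation for each of these 3 lists. In this comparison 12 stem cell genes were lower and 1 higher adjusted over the list alone, and the other 4 lists had the same counts as over all genes. Camera called 13 lists in all. The count of genes was 2000 with the replicate number as a block and 470 when a fold change above 1.2 was required. With the mapping rate as a covariate 6 of 120 named genes lost their call, at a median of 94.9% of their log2 fold change.

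The fold changes of the 3 colitis groups against CON were also compared with each other, across genes, which are not independent replicates. Between DSS and HMLS 1376 genes were higher in both and 1213 lower in both. If the calls were independent 325.7 and 294.2 would be shared, and no gene was called in opposite directions. Between DSS and TM these counts were 1368 and 1108 (268.1 and 208.6 if independent; none opposite), and between HMLS and TM 1323 and 1028 (331.5 and 263.9; 1 opposite). The correlation of fold changes was 0.855, 0.900 and 0.796. In 30 simulations of unchanged groups with shared CON libraries the mean was 0.275, 0.260 and 0.275, and the highest values were 0.818, 0.828 and 0.81. The value of HMLS and TM lay within this range. The simulated colitis libraries were drawn with repeats from a common pool, so a library could enter both groups. The simulated values therefore do not show the effect of shared CON libraries alone. The covariance of the fold changes was 0.180, 0.162 and 0.155, above the highest simulated values of 0.0404, 0.0422 and 0.0796. With the CON libraries split between the comparisons the median correlation over 35 splits was 0.809, 0.811 and 0.683.

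A response score placed each mouse between the CON mean (0 ± 0.115, SD, n = 8) and the DSS mean (1 ± 0.233, SD, n = 5) on the genes called in DSS against CON. It was 0.905 ± 0.228 in HMLS (SD, n = 4) and 0.838 ± 0.173 in TM (SD, n = 5). The difference from DSS was -0.095 for HMLS (two-sided exact permutation test, p = 0.556, 95% interval -0.485 to 0.295) and -0.162 for TM (exact p = 0.23, interval -0.472 to 0.168). HMLS and TM differed by 0.0672 (exact p = 0.627, interval -0.273 to 0.407), and the adjusted p over 3 exact tests was 0.627 for each. In the 3 pairs of TM and DSS mice of the same number, TM was lower in 3 of 3, by -0.115, -0.153 and -0.334 for numbers 5, 6 and 7, with a mean of -0.201 (exact sign-flip test, p = 0.25, the smallest that 3 pairs allow). The sign of the HMLS difference turned without HMLS replicate 7 (0.0104). The genes and weights of the score were chosen on the same DSS mice, which favours higher scores in DSS, also in the 3 pairs. In DSS mice left out of the choice the median score over 20 splits was 0.701, with 0.780 in HMLS and 0.708 in TM. With each DSS mouse scored on genes and weights chosen without it, the DSS mean was 0.821. The HMLS and TM mice kept their scores on genes and weights chosen with all 5 DSS mice. The exact permutation test on these scores gave p = 0.635 for HMLS and 0.937 for TM. Since the groups were not scored on the same genes and weights, this does not rank them.

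The fold changes of each water against DSS were set against those of DSS against CON over the 3655 genes called in the latter, to ask whether the water moved them back toward CON. Pearson's r across genes was -0.270 for HMLS (Spearman's rho -0.176) and -0.543 for TM (rho -0.582). The DSS libraries enter both sides. In 100 simulations of groups without any DSS effect, drawn as above, the mean r was -0.559 and -0.578. A real DSS effect changes the size of r, so the observed r cannot be judged against these values. The covariance was -0.0490 for HMLS, within the 95% range of the simulations (-0.0602 to -3.40e-05), and -0.0839 for TM, beyond it (-0.0614 to 0.000541). The simulations did not choose the called genes anew, so their range leaves out the effect of choosing genes on the same DSS mice. The TM value beyond it therefore does not show a move toward CON. With the DSS libraries split between the sides, the median r over 20 splits was 0.153 for HMLS and -0.0355 for TM. The median covariance was 0.0394 (range -0.168 to 0.221) and -0.00851 (-0.180 to 0.155). Without HMLS replicate 7 the r of HMLS was 0.0286.

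**Figure D3:**
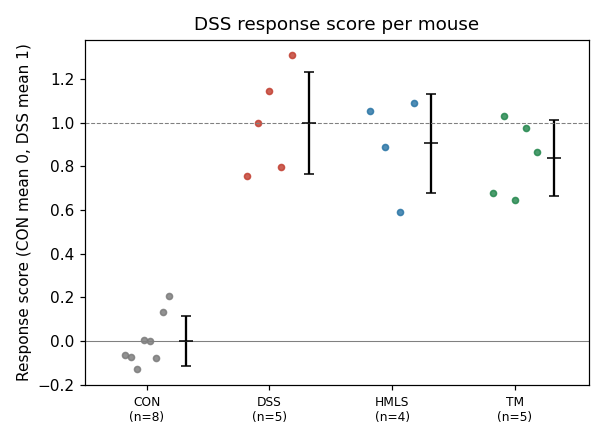
Response score of each mouse, on a scale where 0 is the mean of CON and 1 the mean of DSS, with 1 dot per library in CON (n = 8), DSS (n = 5), HMLS (n = 4) and TM (n = 5); the mark and bar beside the dots are the mean and SD. The HMLS mice lay between 0.589 and 1.09 and the TM mice between 0.644 and 1.03, within or below the DSS range of 0.754 to 1.31. The DSS mice were scored on genes chosen with them, which favours higher DSS scores.

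The named genes were placed on GRCm38. Reg3b lies on chromosome 6 from 78370657 to 78373466 and Lcn2 on chromosome 2 from 32384633 to 32388252. Lgr5 lies on chromosome 10 from 115450311 to 115587780, Ascl2 on chromosome 7 from 142966829 to 142969264, Lyz2 on chromosome 10 from 117277331 to 117282321, C1qa on chromosome 4 from 136895917 to 136898803 and Car3 on chromosome 3 from 14863512 to 14872523. All are annotated as protein-coding genes, and the values are for whole genes.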

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

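The tests of general epithelial genes, of the mapping rate, of the time of day, of glucocorticoid-induced genes and of a water effect were chosen only after the result was seen. The splits of the mice, the test of low values and the test without TM replicate 3 were planned.

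Of 15 intestinal stem cell genes 12 fell in DSS against CON, with a median log2 fold change of -1.05 over the 15. A smaller share of epithelium would lower general epithelial genes alike, but their median was 0.194 (median absolute deviation 0.241, 20 genes). Genes of at least 5 FPKM in CON had a median of -0.862 (10 genes), which argues against low values as the source, and the median in TM against CON was -0.964, where the mapping rate was not lower than in CON, which argues against the mapping rate as the whole source. Of the 20 general epithelial genes 6 are also in the preset lists. An effect of colitis, which the design names, may explain the pattern and stays open as a hypothesis, and no test here separates fewer stem cells from lower expression per cell.

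Of 17 circadian clock genes 7 rose in DSS against CON, with Per1 and Nfil3 among them (camera adjusted p = 0.0022; adjusted p = 0.641 with an estimated correlation). A different time of day at tissue collection is a possible account. The 8 evening-phase genes had a mean log2 fold change of 0.868 ± 0.0736 (SE over genes), and 3 of them passed the threshold. The 3 morning-phase genes had a mean of -0.24 ± 0.107, and none passed in DSS against CON. Per1 and Nfil3 are in neither of these lists, so the means do not cover them. Exposure to glucocorticoids is another possible account. Of 20 glucocorticoid-induced genes 13 rose and 2 fell, where 2.8 were expected to rise (one-sided exact hypergeometric p = 2.28e-07). This list was written after results had been seen, and 10 of the 20 are also in the preset lists. The test also treats genes of the same mice as independent. Its p therefore cannot decide for this account. The times of collection are not given in the sources used here, so neither these nor an effect of colitis itself was excluded.

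Macrophage, MHC class II and B cell genes were lower in HMLS than in TM by camera, with a median log2 fold change of -0.839 over 36 genes. TM replicate 3 alone was not the source, since without it the median was -1 over 31 genes. A different effect of the waters on inflammation may account for it, but the smallest adjusted p of the 3 lists with an estimated correlation was 0.18, so a difference in these lists beyond the spread between mice was not shown. Camera called 23 lists in the real split and also 23 in the highest of the others. In 3 of 100 splits, the real one included, as many lists were called, so few regroupings of the mice gave this number at the preset correlation. Chance was not excluded, and these splits do not test the 3 lists themselves.

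Camera gave adjusted p values below 0.05 for the following lists between HMLS and TM. Lower in HMLS were macrophage (1.47e-13), B cell (5.41e-08), MHC class II (1.17e-07), NF-kB target (6.18e-07), goblet cell (1.08e-05), extracellular matrix (3.08e-05), acute inflammation (4.87e-05), metalloprotease (7.11e-05), plasma cell (0.000172), endothelial (0.000215) and antimicrobial genes (0.000328). Proliferation (0.00382), regenerating epithelium (0.00506), T and NK cell (0.00727), glycolysis (0.0307), immediate early (0.034), interferon-induced (0.0427) and neutrophil genes (0.0488) were also lower. Higher in HMLS were adipose (3.08e-05), xenobiotic metabolism (0.000176), smooth muscle (0.000703), calcium and magnesium (0.00382) and clock genes (0.00753). With an estimated correlation the adjusted p lay between 0.18 and 0.68, and none of these differences was called. Without TM replicate 8 the interferon list turned to higher in HMLS (0.0247), and its call ended without HMLS replicate 3, 6 or 8 (0.287, 0.0858 and 0.0917). Single libraries also ended the calls of the neutrophil list (without HMLS 7, TM 3, TM 6 or TM 7, 0.0554 to 0.312), proliferation (HMLS 3, HMLS 6 or TM 3, 0.147 to 0.395), regenerating epithelium (HMLS 6 or TM 3, 0.0751 and 0.0515) and smooth muscle (HMLS 3, 0.13). The same held for glycolysis (HMLS 3, HMLS 8, TM 3 or TM 7, 0.0579 to 0.145), clock (HMLS 3, HMLS 8 or TM 3, 0.0722 to 0.147) and immediate early genes (HMLS 6, HMLS 7, TM 7 or TM 8, 0.0652 to 0.14).

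Single libraries stood apart from the rest of their group in 13 of 240 groups of values, where chance gives 12. The measure is the gap to the nearest library divided by the range of the group. Of the 13, 5 were in CON replicate 8 and 3 in TM replicate 3, so the total does not show that no library is unusual. CON replicate 8 also had the fewest genes of at least 1 FPKM in CON (12797). Without it 3762 genes passed in DSS, 4808 in HMLS and 3750 in TM against CON. In TM replicate 3 the proliferation score (0.879) was 0.629 against -0.799 to -0.626 in the others, Car4 (0.791) was 4.65 against 7.22 to 7.89 on the log2 scale, and Cxcl1 (0.794) was 3.57 against 1.51 to 1.94. In TM replicate 8 the score of interferon-induced genes (0.881) was 2.32 against -0.494 to -0.158. In CON replicate 8 the metalloprotease score (0.667) was -0.311 against -0.0407 to 0.0944, Igj (0.697) was 2.92 against 5.999 to 7.34, Nxpe2 (0.64) was 4.22 against 5.56 to 6.32, Cldn8 (0.584) was 5.14 against 5.72 to 6.13, and Mzb1 (0.633) was 0.202 against 1.54 to 2.32. Il1b in DSS replicate 7 (0.765) was 3.35 against 0.688 to 1.31, and Mmp10 in CON replicate 4 (0.683) was 1.18 against 0.0822 to 0.43. Tff3 in HMLS replicate 8 (0.851) was 9.73 against 10.19 to 10.26, and Trim27 in HMLS replicate 7 (0.836) was 3.99 against 3.73 to 3.78.

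Other splits of the same mice gave fewer genes than the real one for DSS against CON (3655, and at most 102 elsewhere), HMLS against CON (4565, at most 1697) and TM against CON (3510, at most 914). In each of these only 1 of 100 splits, the real one, gave as many, so none of the other splits drawn reached the real count. For HMLS against DSS, TM against DSS and HMLS against TM the real split gave 0 genes, a number that each of the 100 splits must reach, so these splits say nothing about chance. The highest of the others was 2006 genes for HMLS against DSS, in a split of DSS replicates 5 and 7 and HMLS replicates 3 and 8 from the rest, 731 for TM against DSS and 1 for HMLS against TM. The splits with 2006 and 731 genes followed the first principal component, which the groups without CON do not describe. For HMLS against DSS the libraries named lay at 31.15 or more on it and the rest at 17.44 or less. For TM against DSS, DSS replicates 5 and 7 and TM replicates 5, 7 and 8 lay at 19.41 or more. The rest of that split lay at 7.144 or less. For TM against DSS the 3 pairs of one number were parted in 19 splits, whose highest other count was 0, and splits that kept a pair together reached 731. Since the split with 731 genes also followed the first principal component, it does not show an effect of pairing.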

How the results depend on the processing

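The mapping rate covariate and the paired test of the response score were chosen only after the result was seen, and the other settings named here were planned. The counts of genes against CON stayed within 1.5 times their main value under the settings not named here. The count of DSS against CON was 495 when a fold above 1.2 was required (a stricter null by construction), 2176 with the replicate block and 26 with the mapping rate as a covariate, a rate that differs between these groups. With this covariate 129 of 133 named calls were lost in DSS, 37 of 148 in HMLS and 6 of 120 in TM against CON, at a median of 74.9%, 83.5% and 94.9% of their log2 fold changes. HMLS against CON gave 1034 and 753, and TM against CON 470 and 2000, with the fold minimum and the block. Leaving out 1 library gave 2493 to 4166 genes for DSS against CON, 0 to 1 for HMLS against DSS, 0 in each case for TM against DSS, 0 to 3 for HMLS against TM, 3106 to 4808 for HMLS against CON and 2501 to 4170 for TM against CON. The correlation of HMLS against DSS with DSS against CON ran from -0.4825 to 0.02855 and, with the DSS libraries split, had a median of 0.1529. That of TM ran from -0.6925 to -0.3977, and was -0.3841 over all kept genes and -0.03552 with the split. The response score of HMLS minus DSS ran from -0.1831 to 0.01039 and that of TM minus DSS from -0.2375 to -0.1137, with -0.2005 in the 3 pairs of the same number as a block. In these differences the DSS mice were scored on genes chosen with them. With the shared group split the correlations of fold changes were 0.8092, 0.811 and 0.6834 against CON, and -0.2537 for HMLS and TM against DSS. The sign of the last was turned by the split, since its value with the DSS libraries shared was 0.212, where simulations gave a mean of 0.446. The cause was not tested except where libraries were shared by construction. In TM against DSS the replicate block turned the lists of extracellular matrix (adjusted p = 0.613), metalloproteases (0.941) and oxidative phosphorylation (0.0058); of 41 lists it gained 5 calls and lost 5, all named with that comparison, and it changed no call of 170 named genes. The proliferation list of TM against DSS turned without DSS replicate 1 (range of adjusted p over libraries left out 0.000791 to 0.656). The list of interferon-induced genes turned without TM replicate 8 in TM against DSS (range 1.19e-07 to 0.689), HMLS against TM (0.00303 to 0.287) and TM against CON (0.000221 to 0.921), as did its score in TM against CON (-0.3334 to 0.3705). Over the settings that keep all libraries, calls of named genes were lost in 681 cases and gained in 59. Those of lists were lost in 172 and gained in 37 without a turn in direction, and 3 more cases, not in these counts, turned. With 1 library left out these numbers were 371 and 97 for named genes and 100 and 90 for lists, and 4 more cases of lists, not in these counts, turned. Values that were not called changed sign in 314 cases for named genes and 180 for lists. Libraries of one number correlated from -0.201 to 0.324 in DSS against CON, at -0.326 and 0.326 in HMLS against DSS, from -0.227 to 0.0478 in HMLS against TM, from -0.108 to 0.0707 in HMLS against CON and from -0.00341 to 0.203 in TM against CON. The planned edgeR and DESeq2 tests were not run, since they need counts per gene. Of the named genes called against CON, 28 of 133 in DSS, 32 of 148 in HMLS and 27 of 120 in TM lost the call without some single library. Depth per gene is unknown, so no limit from depth could be set.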

Other observations

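All lists of this part were written only after the results were seen. The lists of histone, collagen and heat shock genes were not tested for enrichment. Of 25 canonical histone genes, which are transcribed in S phase without a poly(A) tail, 25 fell in HMLS against CON (median log2 fold change -2.18), 11 in TM against CON (-1.28) and 3 in DSS against CON (-1.11). The histone genes did not pass the threshold in HMLS against DSS, where their median was -1.03 with all 25 tested, nor in TM against DSS (-0.07) or HMLS against TM (-0.93). Of 13 collagen genes, 7 of which are also in the preset lists, 8 fell in DSS (-0.85), 12 in HMLS (-1.21) and 5 in TM (-0.60) against CON. Of 10 heat shock genes 6 fell in DSS (-0.87), 6 in HMLS (-0.85) and 10 in TM (-0.77), and none rose in any of these comparisons.

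Of 20 general epithelial genes 6 rose in DSS, 4 in HMLS and 6 in TM against CON, and none fell. Of 20 glucocorticoid-induced genes 13 rose and 2 fell in DSS, 11 rose and none fell in HMLS, and 15 rose and none fell in TM. Of the 8 evening-phase clock genes 3 rose in DSS, 6 in HMLS and 2 in TM, and of the 3 morning-phase genes none rose and 1 fell, in TM.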
